A study of Oryza sativa Japonica Group with 36 samples.

How the data were processed

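Shoot RNA of rice seedlings was measured on 36 one-colour Agilent oligonucleotide arrays, in 12 groups of 3 arrays. For each of the nutrients nitrogen (N), phosphorus (P) and potassium (K) there was a control set and a set at 4, 16 and 64 times the control concentration of that nutrient. Groups, doses and replicate numbers were taken from the labels. The labels place the control arrays in experiments on nutrient deficiency, so it is not certain that control and treated seedlings were grown and hybridised together.

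The scanner output of the 27 treated arrays held spot intensities on a linear scale, deposited as Agilent Feature Extraction 10.5.1.1 gave them per the file headers. These intensities were background-subtracted by that software per the file headers. A table of log2 values of all 36 arrays was also deposited. On the 27 treated arrays each value of that table equalled log2 of the processed signal minus the 75th percentile of the array, with a largest difference of 4.88e-08. For the 9 control arrays no scanner file was used, so of their scale it is known only that each 75th percentile is 0, and their background correction, slides and scan days stayed unknown. Column medians lay between −2.53 and −2.37. The direction needs no choice on one-colour arrays. An annotation of the array gave each probe a locus of the Rice Annotation Project (RAP) and a description, both of the age of the array design.

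Each array had 45151 spots, of which 1417 were control spots and 42105 were gene spots of 41889 probes for 29689 loci. Control spots were left out, and 0 gene spots were saturated. Spots marked as outliers (4 to 256 per treated array) were left out of the scanner values only. They stayed in the table of log2 values and so in every comparison that used it. On the treated arrays 81.7% to 88.6% of gene probes were well above background, and the raw 75th percentile lay between 3031 and 5491 intensity units. The detection level was −7.40 on the log2 scale, the 95th percentile of values of probes not well above background on the treated arrays. A gene entered the tests if the mean of at least 1 group lay above that level, which kept 26451 genes. Where a locus had more than 1 probe (7796 loci), the probe with the highest mean over all arrays was used. The number of arrays limits the precision.

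Treated groups were compared with the control of their nutrient on the table of log2 values. One limma fit of the 12 group means over all 36 arrays was used, without covariates (limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The same fit gave the differences between the x64 responses of different nutrients and the differences between the control sets. The x64 and x4 groups were compared on the scanner values of the 27 treated arrays, log2 of the processed signal minus the 75th percentile of the array, for 25103 genes well above background on all 3 arrays of at least 1 group. Every adjusted p of a gene comes from these limma fits. A standard error (SE) is that of the log2 difference, and every group mean has n = 3 arrays. Fold values are 2 to the power of the log2 difference. Where the probe used for a gene was not above background on any array of a group, or its group mean lay below the mean of the lowest values above background on those arrays, the fold is a bound, "at least". The brighter group's mean was then set against the mean of, per array, the higher of the gene's own value and the lowest value above background. For control arrays, which had no scanner marks, the detection level stood in for those marks and values. No fold is given where both groups were below background.

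A total of 28 gene lists, holding loci and words in descriptions, were tested with camera at a preset inter-gene correlation of 0.01. Their names are nitrogen uptake, nitrogen assimilation, phosphate starvation, potassium and sodium transport, sulfur uptake and assimilation, iron acquisition, iron storage, zinc transporters of the ZIP family, dehydration with salt and abscisic acid, defence proteins, phytoalexin synthesis, WRKY transcription factors, jasmonate, photosystems and light harvesting, carbon fixation, chlorophyll synthesis, chlorophyll breakdown and senescence, starch and sugar, type-A cytokinin response regulators, glutathione S-transferases, class III peroxidases, cytosolic ribosomal proteins, heat shock proteins, cell division, cell wall expansion, circadian clock, root markers and reference genes. Of the listed loci, 35 were left out because the old array description did not match the expected words, and 4 were not on the array. Adjustment was over all 252 pairs of list and comparison for treated against control. Differences between responses and between control sets were adjusted separately, each over its own, smaller number of pairs. An estimated correlation and the fry test were alternatives. Members were counted as changed after adjustment over all genes and also after adjustment over the list alone.

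The lists, the tests, the samples in each fit, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each nutrient at x64, the 10 largest rises and the 10 largest falls among genes with a described function that passed the threshold, had all 3 treated arrays beyond all 3 control arrays and lay above the detection level in the higher group. It adds up to 4 members of each list with the largest absolute change, of which the text names a part. For each other comparison it takes 3 rises and 3 falls. Symbols are those of the lists, and other genes carry the description of the array annotation. The reference table of gene names used here (assembly ASM3414082v1) holds no RAP loci, so 0 loci were matched to it and no coordinates are given.

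The alternatives fixed then were quantile normalization, no filter on dim probes, a 2-fold minimum, every probe on its own, the mean of a gene's probes, other probes of named genes, the replicate number as a block, only the arrays compared, an intensity trend with a robust prior, each array left out in turn, and all 9 control arrays as the control. For the scanner values, normexp background correction with an offset of 50, followed by quantile normalization, and the slide as a fixed or random block belonged to the same set. The random block used duplicateCorrelation with statmod 1.5.0. Centring on the median, keeping only genes averaging at least 4 times the detection level, a block for replicates within each nutrient, and lists corrected for wrong matches were chosen after seeing the data. The largest correction was to the list named cell division, where 361 of 475 loci were wrong matches of a word in the description and 114 remained.

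The limma fits named here were tried on simulated values drawn around each gene's mean, after loading, probe choice and filtering, which were not tested. The simulation held no differences between sets or batches, and 7 to 15 unchanged genes were called per comparison. In each, 100 genes were changed 2-fold and 100 were changed 4-fold. At x64 against control the tests called 79 and 91 of them for N, 79 and 92 for P, and 84 and 92 for K, among 26451 genes. For the difference between the x64 responses of N and P they called 67 and 94, for N control against P control 85 and 91, and for N x64 against N x4, among 25103 genes, 85 and 93. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, principal components and fits were computed in R, and figures were drawn with matplotlib 3.10.9. Probes for microRNAs (510) were left out of the gene tests.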

Results

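Shoots of rice (Oryza sativa) cultivar Nipponbare were sampled after 5 days at 4, 16 or 64 times (x4, x16, x64) the control concentration of 1 macronutrient. Seedlings were 7 days old at the start and grew in Yoshida solution, a standard hydroponic medium for rice, diluted 5-fold. Nitrogen (N) was raised with ammonium nitrate, phosphorus (P) with sodium dihydrogen phosphate and potassium (K) with potassium sulfate, so sodium rose together with P and sulfate together with K. Each nutrient had its own control set, and each of the 12 groups had 3 arrays, 36 in all. Levels are log2 signals relative to the 75th percentile of the array. Of the gene probes, 83.5% to 88.3% lay above the detection level of −7.40 on each array. Replicates were not described as separate cultures, so p-values measure only the spread between these samples, which may be technical.

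The arrays lay mostly by nutrient. The first principal component held 29.8% of the variance and set the treated P arrays apart from K, and the second held 18.7% and set all N arrays but N x64 replicate 3 apart from the others. Within K, K control 1 and K x4 replicates 1 and 2 lay at 8.0, 16.5 and 12.4 on the second component, while the other 2 K control arrays lay at −24.4 and −22.4 and K x4 replicate 3 at −28.2. P x64 replicate 1 lay at 58.6 on the first component, near the P x4 and x16 arrays (61.2 to 85.3), and P x64 replicates 2 and 3 lay at 19.6 and 15.8. All treated arrays of a nutrient were scanned on 1 day, a different day for each nutrient, and the slides and days of the control arrays were not known. Batch and treatment therefore cannot be told apart between nutrients or, for P and K, in any comparison with a control set. For N, the x4 arrays, scanned on the same day as x64, differed from the same control in 95 genes, against 4197 at x64. This argues against scan day or the control set as the source of most N x64 changes. Slide stays open there, since all N x64 arrays lay on 1 slide without x4 arrays. N x16 replicate 3 shared that slide, but 1 array cannot separate slide from dose.

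**Figure D1:**
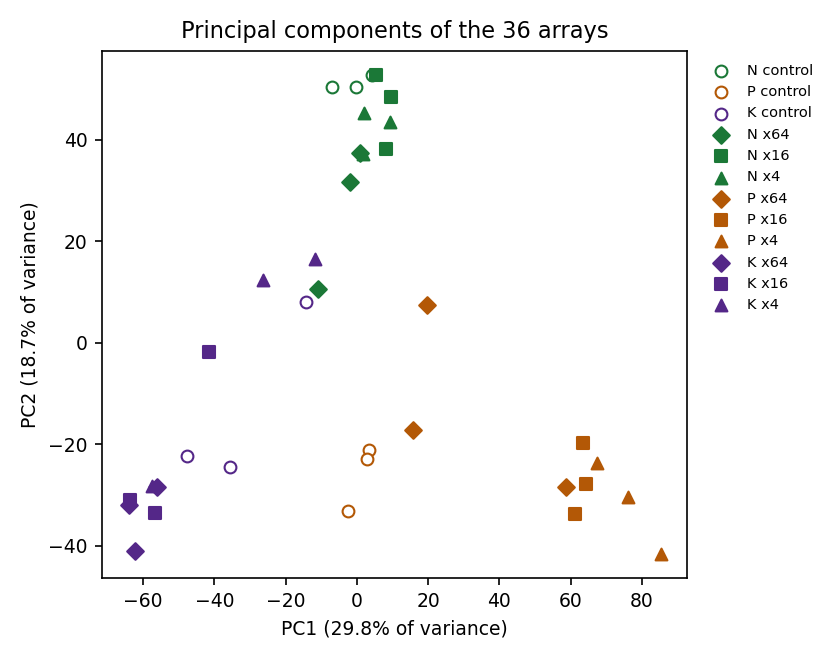
First and second principal components of the log2 levels of 26451 genes on 36 arrays, with 29.8% and 18.7% of the variance on the axes; each point is 1 array, coloured by nutrient and shaped by dose. Except for N x64 replicate 3, the N arrays lie highest on the second component (31.7 to 52.8), and the P x4 and x16 arrays lie farthest right on the first (61.2 to 85.3).

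At N x64 single genes of nitrogen metabolism and transport changed, some upward and some downward. Asparaginase (Os04g0650700), which releases ammonium from asparagine, fell 7.28-fold at x64 (log2 −2.86, SE 0.14, adjusted p = 2.23e-13, 3 arrays per group). An amino acid transporter gene (Os03g0254200) fell 6.37-fold and a low-affinity sulfate transporter gene (Os03g0195300) fell 5.83-fold, whereas sulfate transporter 3.1 (Os01g0719300) rose 2.45-fold. The ammonium transporter genes AMT1;1 (Os04g0509600) and AMT1;3 (Os02g0620600) fell 1.75-fold and 1.62-fold. Among nitrate reductase genes NIA1 (Os08g0468100) fell 1.79-fold and NR1 (Os02g0770800) rose 3.29-fold, and the asparagine synthetase gene AS1 (Os03g0291500) rose 2.53-fold. Of 16 nitrogen assimilation genes 3 rose and 5 fell (4 and 5 adjusted over the list alone), and of 9 nitrogen uptake genes 1 rose and 2 fell (1 and 2 adjusted over the list alone). Neither list passed the camera test (adjusted p = 0.335 and 0.960). In the sulfur list 2 of 16 genes rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.800). The AS1 call ended without N control 1 (log2 1.1, adjusted p = 0.109) or N x64 replicate 3 (1.17, 0.0898), and that of NR1 ended against all 9 control arrays (0.87, 0.0603).

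The ferritin genes Fer1 (Os11g0106700) and Fer2 (Os12g0106000), which encode the plastid iron store, fell 4.01-fold and 3.59-fold at N x64 (log2 −2.00 and −1.84, SE 0.11 and 0.10, adjusted p = 1.28e-12 and 2.01e-12). Both measured members of the iron storage list fell, also when adjusted over the list alone (median log2 −1.92, adjusted p = 4.67e-08, and adjusted p = 0.0284 with an estimated correlation). The iron regulator gene IRO2 (Os01g0952800) rose at least 1.89-fold, the metal transporter gene NRAMP1 (Os07g0258400) 4.56-fold and IRO3 (Os03g0379300) 1.68-fold. They were the 3 risen of 9 iron acquisition genes (3 rises and 1 fall adjusted over the list alone), a list that did not pass the camera test (adjusted p = 0.182). These values depended on the N control set. Against all 9 control arrays Fer1 and Fer2 stood at −0.71 and −0.60 (adjusted p = 0.229 and 0.291), the iron storage list at adjusted p = 0.363, and IRO2, NRAMP1 and IRO3 turned to −0.25, −0.73 and −0.45 (adjusted p = 0.910, 0.659 and 0.419). Without N x64 replicate 3 the NRAMP1 call ended (1.72, adjusted p = 0.0820).

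Type-A response regulators, which are induced by cytokinin and dampen its signal, were mostly lower at N x64. Of 8 measured, 6 fell (6 adjusted over the list alone), with a median log2 of −0.76 (adjusted p = 2.94e-09, but adjusted p = 0.0555 with an estimated correlation). RR10 (Os12g0139400) fell 2.62-fold, RR9 (Os11g0143300) 2.31-fold, RR1 (Os04g0442300) 2.08-fold and RR6 (Os04g0673300) 1.79-fold. Of 57 glutathione S-transferases, enzymes of detoxification, 13 rose (16 higher and 1 lower adjusted over the list alone; adjusted p = 7.10e-03, and adjusted p = 0.852 with an estimated correlation). Among them GSTU31 (Os10g0481300) rose 3.20-fold, GST 30 (Os10g0530900) 2.61-fold and GST 8 (Os01g0353400) 2.25-fold. Of 111 defence genes 22 rose and 5 fell (25 and 7 adjusted over the list alone; adjusted p = 0.0243, and adjusted p = 0.865 with an estimated correlation), with a chitinase gene (Os05g0399400) up 6.39-fold. Of 34 genes of dehydration and abscisic acid 7 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.0417, and adjusted p = 0.865 with an estimated correlation). A late embryogenesis abundant (LEA) gene (Os03g0322900) rose 3.81-fold, while a group 1 LEA gene (Os06g0110200) and DREB1A (Os09g0522200) fell 2.36-fold and 2.08-fold. Of 37 jasmonate genes 4 rose (4 adjusted over the list alone; adjusted p = 0.0417, and adjusted p = 0.865 with an estimated correlation). WRKY64 (Os12g0116700) rose 7.25-fold in a list of 69 WRKY factors with 8 rises and 5 falls (8 and 5 adjusted over the list alone; adjusted p = 0.344). Against all 9 control arrays the list calls for defence (adjusted p = 0.304), dehydration (0.484) and glutathione S-transferases (0.204) ended, that for jasmonate turned (0.225), and the calls of WRKY64 (log2 0.44, adjusted p = 0.770) and GST 30 (0.56, 0.175) ended.

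The largest single change at N x64 was the 121-fold fall of a Myb-domain gene (Os07g0443500), from −0.67 ± 0.37 to −7.59 ± 0.41 (SD, n = 3; log2 −6.92, SE 0.38, limma adjusted p = 1.28e-12). Large rises were seen for a beta-glucosidase aggregating factor gene (Os12g0198700, 20.5-fold), the proteinase inhibitor gene CI2C (Os12g0548700, 18.7-fold), a lipid transfer protein gene (Os04g0415800, 13.7-fold), a Bowman-Birk inhibitor gene (Os01g0127600, 12.7-fold) and a von Willebrand factor domain gene (Os11g0687100, 11-fold). From a control below background, a phosphate-induced protein 1 family gene (Os02g0756600) rose at least 8.55-fold, the protease gene P69F (Os12g0427600) at least 6.69-fold, a P450 gene (Os11g0138300) at least 2.19-fold and a receptor kinase gene (Os05g0463000) at least 1.5-fold. Falls included the homeobox gene OSH15 (Os07g0129700, at least 7.41-fold), a pollen allergen domain gene (Os05g0531200, at least 6.47-fold), a Rubisco large chain family gene (Os04g0516200, 6.82-fold), CYP51 (Os05g0416400, at least 4.22-fold) and an ACC synthase gene of ethylene synthesis (Os01g0192900, at least 2.81-fold). The carbon fixation list as a whole had 1 rise and 3 falls among 21 genes (1 and 3 adjusted over the list alone; adjusted p = 0.905). The root-expressed gene RCc3 (Os02g0662000) fell 6.81-fold and the aquaporin gene PIP2;3 (Os04g0521100) 2.90-fold, while the silicon channel gene Lsi1 (Os02g0745100) rose 1.35-fold, in a root marker list of 4 (1 rise and 2 falls adjusted over the list alone; adjusted p = 0.618). The phosphate-starvation genes SPX6 (Os07g0614700) and PHO1;1 (Os01g0110100) went opposite ways, 3.01-fold down and 2.16-fold up, and the sodium antiporter gene NHX1 (Os07g0666900) fell 1.78-fold. Of 36 phosphate starvation genes 4 rose and 7 fell (4 and 7 adjusted over the list alone), and of 39 genes of potassium and sodium transport 10 rose and 3 fell (13 and 3 adjusted over the list alone).

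Some of these calls ended when 1 array was left out, which also leaves fewer arrays for the test. The OSH15 call (log2 −4.34) ended without N control 1 (−4.44, adjusted p = 0.0670), N control 2 (−3.92, 0.0954), N x64 replicate 1 (−3.44, 0.144) or N x64 replicate 3 (−3.61, 0.137). That of Os05g0531200 (−4.11) ended without N control 2 (−3.56, 0.0679), N x64 replicate 1 (−3.59, 0.0692) or replicate 3 (−3.78, 0.0621), and that of Os04g0516200 (−2.77) without N control 2 (−2.47, 0.0554) or N x64 replicate 3 (−2.22, 0.0875). The Os01g0127600 call (3.67) ended without N control 2 (3.65, 0.0686), N control 3 (3.01, 0.129), N x64 replicate 1 (3.76, 0.0631) or replicate 3 (3.10, 0.134). For RCc3 (−2.77) the log2 change was −1.01 without N control 1 (adjusted p = 0.246), and the call also ended without N x64 replicate 1 (−2.59, 0.0783) or replicate 3 (−2.78, 0.0632). For PIP2;3 (−1.53) it was −1.20 without N control 1 (0.156) and −0.51 without N x64 replicate 3 (0.300). The Lsi1 call (0.43) ended without N control 1 (0.28, 0.188), N x64 replicate 2 (0.41, 0.0600) or replicate 3 (0.40, 0.0812). Against all 9 control arrays the limma adjusted p was 0.621 for CI2C, 0.301 for Os12g0198700, 0.123 for Os11g0687100, 0.875 for Os01g0127600, 0.0864 for the ACC synthase gene Os01g0192900, 0.363 for OSH15, 0.413 for Os05g0531200, 0.207 for RCc3 and 0.268 for Os04g0516200.

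Across N doses the number of changed genes grew. Of 26451 genes tested, 95 changed at N x4 (56 higher, 39 lower), 456 at x16 (368 higher, 88 lower) and 4197 at x64 (2419 higher, 1778 lower), of which 21, 16 and 533 changed at least 2-fold. Of 43 genes of the photosystems and light harvesting 10 rose at x16 (24 higher and 1 lower adjusted over the list alone; median log2 0.25, adjusted p = 5.40e-15, but adjusted p = 0.471 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.213). The list named cell division, of whose 475 loci 361 were wrong matches, had 5 rises and 4 falls among 406 at x16 (7 and 5 adjusted over the list alone; median log2 −0.06, adjusted p = 5.11e-03, and adjusted p = 0.865 with an estimated correlation). That call ended with all 9 control arrays (adjusted p = 0.575) and with the corrected list of 114 loci, chosen after seeing the data (adjusted p = 0.291). The corrected list was called at N x64 (median log2 −0.15, adjusted p = 5.19e-03), P x16 (0.25, 7.33e-07), P x64 (0.17, 9.36e-05) and K x4 (−0.18, 0.0141), each with adjusted p = 0.898 with an estimated correlation. Ribosomal protein genes had a median log2 of −0.13 at x4 and −0.11 at x16 (adjusted p = 1.30e-08 and 1.89e-05, but adjusted p = 0.865 for both with an estimated correlation). The WRKY list had a median log2 of −0.06 at x4 (adjusted p = 0.0478, and adjusted p = 0.865 with an estimated correlation). With quantile normalization 70.3% of the genes changed at x16 were higher, against 80.7%. Of the 368 genes higher at x16, 216 were also higher at x64 (33.7 for independent lists), and of 88 lower genes 50 were also lower (5.92). The covariance of the log2 changes was 0.0591, and 0.0341 for simulated unchanged groups sharing the controls, whereas r across genes was 0.499 against 0.501 simulated. For x4 and x64, 32 of 56 and 9 of 39 were shared (5.12 and 2.62), with a covariance of 0.0504 against 0.0342 and r across genes of 0.4 against 0.5. Genes are not independent replicates, r did not exceed what shared controls alone give, and how much of these excesses comes from them was not resolved, since 3 control arrays cannot be split with 2 in each part. The x4 count was 13, 8 or 5 without N control 1, 2 or 3 and 19, 14 or 24 without x4 replicate 1, 2 or 3. The x16 count was 147, 142 or 135 without N control 1, 2 or 3, 173 without x16 replicate 1 and 275 without replicate 3. The x64 count was 2629 without N control 1 and 2632 without x64 replicate 3. With only the arrays compared, the counts were 0, 10 and 6417 (limma, with 3991 genes at x4 at an unadjusted p under 0.05, and 3316 in the fit of all arrays), and with all 9 control arrays 1054 and 1320 genes were called at x4 and x16.

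**Figure D2:**
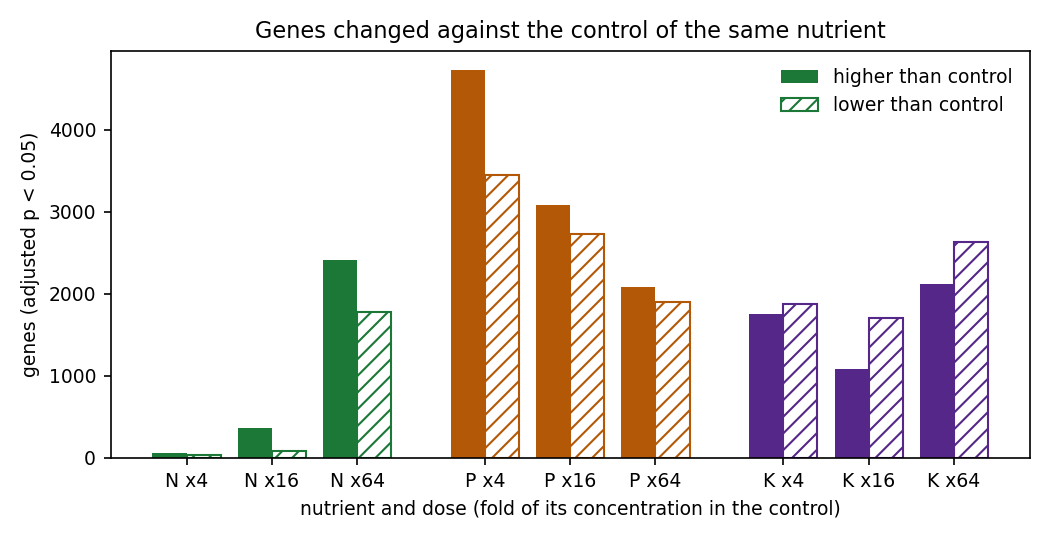
Number of genes higher and lower than the control of the same nutrient (limma adjusted p under 0.05, of 26451 genes), by nutrient and dose; each bar is 1 comparison of 3 with 3 arrays. Counts grew with dose for N (95, 456, 4197), fell for P (8179, 5808, 3984) and were 3624, 2790 and 4749 for K.

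Genes for iron acquisition were higher at every P dose. The nicotianamine synthase genes NAS2 (Os03g0307200) and NAS1 (Os03g0307300), whose product chelates iron for transport, rose 36.2-fold and 35.1-fold at x64 (log2 5.18 and 5.13, SE 0.37 and 0.32, adjusted p = 2.29e-10 and 2.94e-11), after 46.2-fold and 57.2-fold at x4 and 108-fold and 117-fold at x16. The regulator gene IRO2 (Os01g0952800) rose 9.08-fold, 16.4-fold and 9.20-fold with rising dose, the metal transporter gene NRAMP1 (Os07g0258400) 7.02-fold, 13.1-fold and 7.28-fold, and the iron-nicotianamine transporter gene YSL2 (Os02g0649900) 8.59-fold, 9.93-fold and 8.62-fold. Of 9 listed iron acquisition genes 6 rose and 1 fell at x64 (6 and 1 adjusted over the list alone; median log2 2.55, adjusted p = 7.84e-06, and adjusted p = 0.0318 with an estimated correlation). At x4 and x16, 7 rose and 1 fell (7 and 1 adjusted over the list alone; median log2 2.53 and 3.72, adjusted p = 3.82e-05 and 9.07e-08, and adjusted p = 0.0506 and 0.0175 with an estimated correlation). The gene that fell was NAS3 (Os07g0689600, log2 −1.34 at x64), named here after its values were seen. Fer1 (Os11g0106700) and Fer2 (Os12g0106000) fell 2.33-fold and 2.28-fold at x64, 2.33-fold and 2.31-fold at x4, and 2.37-fold and 2.53-fold at x16. The iron storage list, both of whose members fell (both adjusted over the list alone), had a median log2 of −1.21 at x64 (adjusted p = 9.00e-06, but adjusted p = 0.0583 with an estimated correlation, and adjusted p = 0.0658 against all 9 control arrays). At x4 and x16 the list's medians were −1.22 and −1.29 (adjusted p = 1.75e-04 and 2.67e-05, but adjusted p = 0.124 and 0.0765 with an estimated correlation). Another Fer1 probe gave −0.85 at x64 (adjusted p = 0.0757). In the P control arrays Fer1 stood at 4.42, against 5.80 in the N and 3.30 in the K control arrays.

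**Figure D3:**
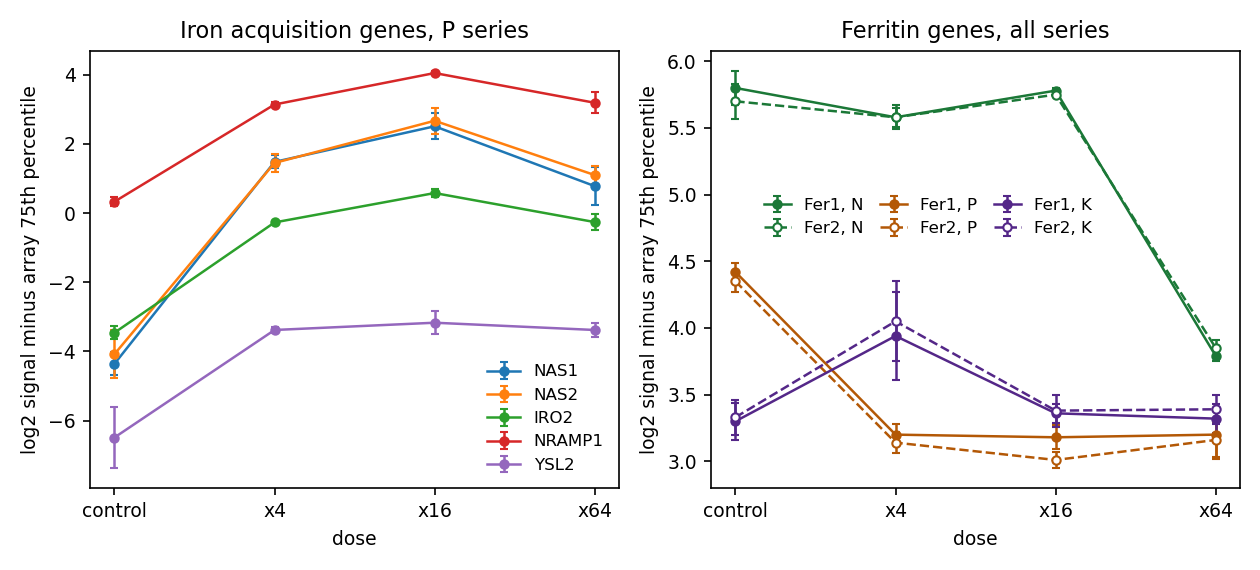
Log2 signal minus the 75th percentile of the array for iron acquisition genes in the P series (left) and ferritin genes in all 3 nutrient series (right), by dose; points are means of 3 arrays and error bars are SD. NAS1 and NAS2 lie above the P control at each dose (log2 5.13 and 5.18 at x64) and the P ferritins below it (−1.22 and −1.19), while the control sets themselves differ, with Fer1 at 5.80 in N, 4.42 in P and 3.30 in K controls.

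Several genes linked to water deficit were higher with P, whose salt also supplied sodium, and some of them also with N and K. The plasma membrane protein gene PM19 (Os05g0381400), induced by abscisic acid, rose 8.13-fold at x64, an embryonic abundant protein gene (Os05g0349800) 14.8-fold, the LEA gene Os03g0322900 3.71-fold and the dehydrin gene RAB16D (Os11g0453900) 3.33-fold. Of 34 dehydration genes 9 rose and 1 fell (14 and 1 adjusted over the list alone; median log2 0.51, adjusted p = 2.41e-03, but adjusted p = 0.523 with an estimated correlation). The list's x64 response did not differ between N and P (camera adjusted p = 0.781) or between P and K (0.512). PM19 and Os03g0322900 were also higher at x64 of N (log2 1.48 and 1.93) and of K (0.97 and 1.48). Os05g0349800 responded more to P than to N or K. The potassium channel gene TPKb (Os07g0108800) rose 1.97-fold and the sodium transporter gene HKT2;1 (Os06g0701700) fell 1.78-fold (another probe gave log2 −0.43, adjusted p = 0.0992), in a transport list of 39 with 9 rises and 3 falls (9 and 4 adjusted over the list alone; adjusted p = 0.259). Of 36 phosphate starvation genes 2 rose and 5 fell (3 and 5 adjusted over the list alone; adjusted p = 0.502). The acid phosphatase gene PAP10a (Os01g0776600) fell 1.48-fold, PHO2 (Os05g0557700), which limits phosphate uptake, rose 1.45-fold, and the phosphate-starvation RNA IPS1 (Os03g0146800) stood at log2 0.65 (adjusted p = 0.367) by its brighter probe and −0.57 by another.

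Among class III peroxidases falls outnumbered rises at P x64, where 22 of 106 fell and 4 rose (26 and 7 adjusted over the list alone; median log2 −0.11, adjusted p = 0.0401, but adjusted p = 0.366 with an estimated correlation), with Os07g0677300 down 8.39-fold and Os04g0688200 down 7.21-fold. This list's call ended with quantile normalization (adjusted p = 0.0616) and with median centring (0.0525). Of 148 cytosolic ribosomal protein genes 74 fell and 1 rose at x4 (86 and 2 adjusted over the list alone) and 15 fell at x64 (13 adjusted over the list alone). The list was called at x64 (median log2 −0.18, adjusted p = 5.88e-08, and adjusted p = 0.865 with an estimated correlation), with S3a (Os12g0406200) down 1.41-fold. Of 12 ZIP zinc transporter genes 3 fell (3 adjusted over the list alone; median log2 −0.15, adjusted p = 0.0441, but adjusted p = 0.317 with an estimated correlation, and adjusted p = 0.0658 against all 9 control arrays). A beta-expansin gene (Os10g0555600), of a family that loosens cell walls, fell 2.58-fold. The cell wall expansion list was called at x4, with 14 falls and 4 rises among 39 (15 and 4 adjusted over the list alone; adjusted p = 0.0471, and adjusted p = 0.865 with an estimated correlation), a call that ended with quantile normalization (0.0694) and all 9 control arrays (0.0508). At x16, 6 of 21 carbon fixation genes fell (6 adjusted over the list alone; median log2 −0.26, adjusted p = 7.10e-03, but adjusted p = 0.724 with an estimated correlation). Jasmonate genes went both ways: at x4, 12 of 37 fell and 5 rose (12 and 5 adjusted over the list alone; adjusted p = 0.0246, but adjusted p = 0.865 with an estimated correlation, and 0.363 against all 9 control arrays), and at x64 a ZIM-domain gene (Os03g0180800) rose 3.97-fold and a lipoxygenase gene (Os11g0575600), near background in both groups, fell (log2 −2.05).

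Other large rises at P x64 were those of ASC1 (Os02g0728300, 11.8-fold), a TGF-beta receptor domain gene (Os01g0871600, 9.86-fold) and a P450 gene (Os09g0275400, 6.07-fold). Of the 10 largest falls, 9 ended below background: an esterase gene (Os07g0526600, at least 11.3-fold), a resistance protein gene (Os03g0258000, at least 2.85-fold), an ARM repeat gene (Os01g0522400, at least 2.77-fold), a chalcone synthase gene of flavonoid synthesis (Os07g0501100, at least 2.64-fold), a ribosomal L4 gene (Os12g0488600, at least 2.37-fold), a glucosyltransferase gene (Os09g0329200, at least 2.34-fold), an aspartic protease gene (Os09g0119300, at least 2.21-fold), a protein kinase gene (Os02g0833000, at least 2.13-fold) and a P450 gene (Os10g0164600, at least 2.03-fold). A transferase gene (Os06g0185500) fell 10-fold. Against all 9 control arrays the calls of these falls ended except that of Os12g0488600, with adjusted p from 0.0515 for Os02g0833000 to 0.235 for Os03g0258000, and those of PAP10a (Os01g0776600, 0.226) and Os11g0575600 (0.283) ended too. The Os07g0526600 call ended without P control 3 (log2 −4.39, limma adjusted p = 0.0755).

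The number of changed genes fell with P dose, from 8179 at x4 (4729 higher, 3450 lower) through 5808 at x16 (3081 higher, 2727 lower) to 3984 at x64 (2087 higher, 1897 lower), of which 1642, 1265 and 734 changed at least 2-fold. Of the rises, 28.9%, 31% and 22.9% (1369, 954 and 478 genes) were of dim genes, those averaging under 4 times the detection level. Dim genes were 5163 of the 26451 genes tested. The number of changed genes also fell with dose when only bright genes were kept, so dim genes were not the whole of the pattern. Probes of random or artificial sequence had a median log2 change of −0.323, −0.634 and −0.899 at the 3 doses. The P control arrays had the highest floor of all sets, with lowest values of −8.71 to −8.58 against −10.4 to −10.1 in the N and −9.64 to −9.35 in the K control arrays. Of genes higher at x16, 1454 were also higher at x64 (243 for independent lists) and 1390 were lower at both (196), with a covariance of 0.199 against 0.0342 simulated and r across genes of 0.731 against 0.499. For x4 and x64 the shared numbers were 1492 (373) and 1181 (247), with a covariance of 0.176 against 0.0349 and r across genes of 0.605 against 0.507, and part of each excess may come from the shared controls. With only the arrays compared the x64 count was 1668 (limma).

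Genes for ribosomal proteins and some genes of chlorophyll synthesis were lower at K x64. Of 148 cytosolic ribosomal protein genes 111 fell (129 fell and 1 rose adjusted over the list alone), with a median log2 of −0.44 (adjusted p = 3.94e-29, but adjusted p = 0.865 with an estimated correlation). The L10a gene (Os01g0860300) fell 1.91-fold (log2 −0.94, SE 0.18, adjusted p = 1.19e-03) and the SA gene (Os07g0616600) 1.64-fold. YGL1 (Os05g0349700), which encodes chlorophyll synthase, fell 1.63-fold, and the magnesium chelatase genes CHLD (Os03g0811100) and CHLI (Os03g0563300) fell 1.44-fold and 1.36-fold. These were the 3 fallen of 7 chlorophyll synthesis genes (3 adjusted over the list alone; median log2 −0.15, adjusted p = 0.0381, but adjusted p = 0.865 with an estimated correlation, and 0.0576 with quantile normalization). Another CHLI probe gave −0.06 (adjusted p = 0.871). A PsbQ family gene of photosystem II (Os02g0578400) fell 2.53-fold, in a list of 43 with 2 rises and 4 falls (1 and 4 adjusted over the list alone; adjusted p = 0.896).

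Genes of ion transport also differed at K x64. The sodium transporter gene HKT2;1 (Os06g0701700) fell 2.51-fold (log2 −1.33, SE 0.18, adjusted p = 7.39e-05), the potassium channel gene SKOR (Os04g0445000) fell 1.78-fold, and MRS2-7 (Os03g0742400), of a magnesium transporter family, fell at least 3.54-fold. In the list of potassium and sodium transport 5 of 39 genes rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.524). The low-affinity sulfate transporter gene Os03g0195300 rose 1.59-fold and an ATP sulfurylase gene (Os03g0743900), which starts sulfate assimilation, 1.58-fold. They were among 4 of 16 sulfur genes that rose (5 rose and 2 fell adjusted over the list alone; adjusted p = 0.259). Phosphate starvation genes included falls of MGD3 (Os08g0299400, 2.12-fold), GDPD2 (Os02g0514500, 1.93-fold), SPX6 (Os07g0614700, 1.55-fold) and IPS1 (Os03g0146800, log2 −1.49), and the list of 36 had 2 rises and 6 falls (2 and 6 adjusted over the list alone; adjusted p = 0.948). NAS1 (Os03g0307300) fell 3.54-fold and RR1 (Os04g0442300) 1.41-fold. Type-A response regulators had 4 falls among 8 (4 adjusted over the list alone; adjusted p = 0.0506). The calls of SKOR (log2 −0.56, adjusted p = 0.0950) and IPS1 (−1.08, 0.167) ended without K control 1, and that of IPS1 also without K x64 replicate 1 (0.0751), 2 (0.0670) or 3 (0.0502). Another IPS1 probe gave 0.03 and another RR1 probe −0.28 (adjusted p = 0.0556). MGD3 (adjusted p = 0.244) and SPX6 (0.184) were not called against all 9 control arrays.

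The largest rises at K x64 were those of a glycine-rich protein gene (Os02g0587000, at least 7.39-fold from a control below background), PR1a (Os07g0124900, 13.4-fold), a family 18 glycoside hydrolase gene (Os08g0519300, 12.5-fold), a class III chitinase gene (Os11g0701800, 11.9-fold), an O-methyltransferase gene (Os09g0344500, 7.15-fold), a TolB domain gene (Os03g0403400, 6.23-fold) and a glucosyltransferase gene (Os09g0518200, 6.18-fold). Also from such a control, a LATERAL ORGAN BOUNDARIES gene (Os02g0820500) rose at least 2.05-fold, the P450 gene CYP92A1 (Os09g0441100) at least 1.65-fold and an Exo70 gene (Os08g0519900) at least 1.47-fold. Falls were those of a pollen allergen family gene (Os05g0246300, at least 4.72-fold), the peroxidase gene POC1 (Os07g0677500, 9.47-fold), a fasciclin domain gene (Os02g0308400, 9.13-fold), a serine carboxypeptidase gene (Os03g0392600, 7.75-fold), a plastocyanin-like gene (Os07g0105000, at least 4.41-fold), a tRNA isopentenyltransferase gene (Os03g0356900, at least 2.63-fold), an RNA-binding protein gene (Os05g0223300, at least 2.52-fold), a P450 gene (Os12g0134900, at least 2.16-fold) and a disease resistance gene (Os10g0161400, at least 1.95-fold). The diterpene synthase gene CPS4 (Os04g0178300), of phytoalexin synthesis, fell at least 3.72-fold, and 2 of 4 phytoalexin genes fell (3 adjusted over the list alone; median log2 −0.73, adjusted p = 0.0261, but adjusted p = 0.422 with an estimated correlation, and 0.144 against all 9 control arrays). Of 111 defence genes 11 rose and 10 fell (12 and 11 adjusted over the list alone; adjusted p = 0.524).

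Some of these K calls likewise ended when 1 array was left out. Without K control 1 the log2 change of PR1a (Os07g0124900) was 3.00 (adjusted p = 0.0903), against 3.74 with all arrays. Os11g0701800 then stood at 3.16 (0.0621) against 3.57, Os09g0344500 at 2.3 (0.195) against 2.84, Os03g0403400 at 1.5 (0.1) against 2.64 and Os05g0246300 at −2.70 (0.0638) against −3.26. The Os09g0344500 call also ended without K control 2 (2.61, 0.120), K x64 replicate 1 (3.15, 0.0738), 2 (3.00, 0.0874) or 3 (2.36, 0.156), and with quantile normalization (2.79, 0.0513). Calls further ended without K x64 replicate 1 for Os11g0701800 (3.33, 0.0505), without replicate 2 for Os08g0519900 (2.07, 0.0522) and Os09g0441100 (1.81, 0.0568), and without replicate 3 for Os08g0519900 (1.77, 0.0607) and Os05g0246300 (−2.30, 0.0704), limma adjusted p throughout. Another PR1a probe gave log2 0.47 (adjusted p = 0.624), and Os12g0134900 (0.0529) and Os10g0161400 (0.0544) were not called against all 9 control arrays.

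At K x4 3624 genes differed from the K control (1751 higher, 1873 lower), 2790 did at x16 (1080 higher, 1710 lower) and 4749 at x64 (2116 higher, 2633 lower), of which 353, 279 and 584 changed at least 2-fold. Among the x4 arrays, replicates 1 and 2 lay apart from replicate 3 on the second component, near K control 1. At x4, 19 of 43 photosystem and light-harvesting genes rose (24 adjusted over the list alone; median log2 0.25, adjusted p = 2.20e-11, but adjusted p = 0.742 with an estimated correlation, and 0.153 with quantile normalization). Both ferritin genes rose at x4 (2 adjusted over the list alone; median log2 0.68, adjusted p = 1.67e-03, but adjusted p = 0.276 with an estimated correlation), a direction that turned against all 9 control arrays (adjusted p = 0.614). Heat shock genes had 16 rises and 6 falls among 134 at x4 (20 and 7 adjusted over the list alone; median log2 0.06, adjusted p = 0.0300, but adjusted p = 0.0986 with an estimated correlation, and 0.0754 with quantile normalization). At x16, 2 of 7 chlorophyll synthesis genes fell (5 adjusted over the list alone; adjusted p = 2.49e-03, and adjusted p = 0.471 with an estimated correlation), and of 42 starch and sugar genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.0473, but adjusted p = 0.865 with an estimated correlation, and 0.127 against all 9 control arrays). Clock genes had 3 rises among 7 at x64 (4 adjusted over the list alone; adjusted p = 0.104), senescence genes had a median log2 of 0.18 (adjusted p = 0.506), and of 4 reference genes 1 fell (1 adjusted over the list alone; adjusted p = 0.136). With each array centred on its median 63.7% of the genes changed at x4 were higher, against 48.3%.

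Between K doses, of genes higher at x16 474 were also higher at x64 (86.4 for independent lists) and 853 were lower at both (170), with a covariance of 0.114 against 0.0342 simulated and r across genes of 0.687 against 0.503. For x4 and x64 the shared numbers were 593 (140) and 699 (186), with a covariance of 0.0735 against 0.0341, but r across genes was 0.427 against 0.502, below what shared controls alone give. For x16 and x64 both values exceeded the simulated ones, so chance spread of the shared controls gives at most part of that excess. For x4 and x64 the covariance alone exceeded the simulated one, so control spread of the simulated size gives at most part of it. The lower r does not decide this, since changes at only 1 dose also lower r. A spread of the K controls wider than that of all groups together was not simulated. A K control set that differs as a whole was not simulated and may add to both. The K x4 count was 1780 or 1821 without K control 2 or 3 and 1752 or 2131 without x4 replicate 1 or 2. Without K control 1 the x16 count was 1796 and the x64 count 2797, and without x64 replicate 1 or 2 the x64 count was 2859 or 2960. With only the arrays compared the counts at x4, x16 and x64 were 659, 94 and 1371 (limma), and with all 9 control arrays 6099 genes were called at x16.

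**Figure D4:**
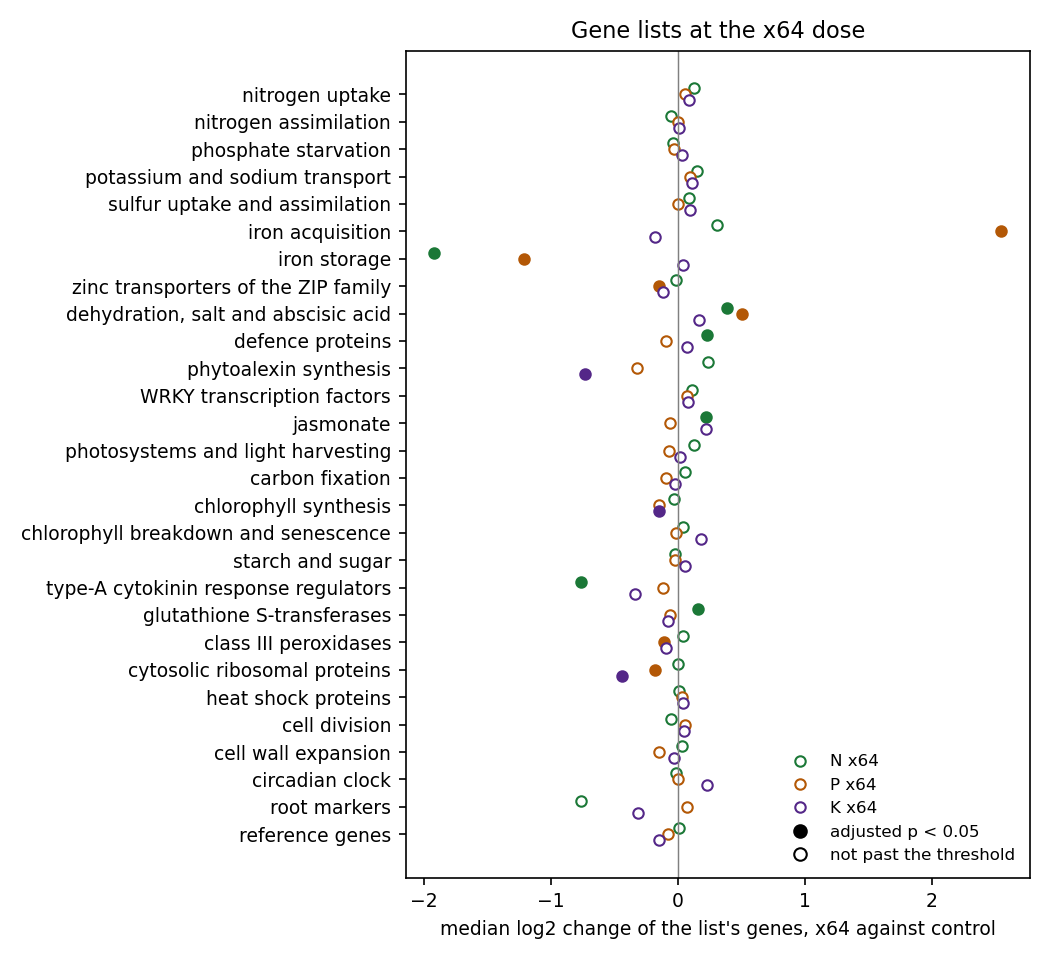
Median log2 change at x64 against control of each of the 28 gene lists, by nutrient, with filled points where the camera adjusted p was under 0.05. Iron acquisition at P (2.55), iron storage at N (−1.92) and P (−1.21), type-A response regulators at N (−0.76) and ribosomal proteins at K (−0.44) are among the filled points.

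The comparison of x64 with x4 uses treated arrays only. For N, the lipid transfer protein gene Os04g0415800 was 17.3-fold higher at x64 than at x4 (log2 4.11, SE 0.52, adjusted p = 1.78e-05), the glucosyltransferase gene Os09g0518200 13.5-fold and a ferric reductase-like gene (Os04g0578600) at least 6.18-fold, while the Myb gene Os07g0443500 was 73.4-fold lower, asparaginase (Os04g0650700) 7.01-fold lower and ACC synthase (Os01g0192900) at least 2.73-fold lower. For P, an anionic peroxidase gene (Os04g0689000) was 7.32-fold higher, DREB1B (Os09g0522000), a regulator of cold response, 5.06-fold higher and an expansin gene (Os06g0718100) at least 3.41-fold higher, while a protease gene (Os10g0474600), an alpha-glucosidase gene (Os01g0921200) and a NAM-domain gene (Os11g0512200) were at least 4.58-fold, 5.84-fold and 5.08-fold lower. For K, IRO2 (Os01g0952800) was at least 10.2-fold higher, an arginine decarboxylase gene of polyamine synthesis (Os04g0107600) 15.9-fold and PR1a (Os07g0124900) 13.7-fold higher, while POC1 (Os07g0677500) was 15.3-fold lower and Os05g0246300 and Os07g0105000 were at least 8.1-fold and 4.57-fold lower.

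Of 25103 genes, 3480 differed between N x64 and N x4 (1974 higher, 1506 lower at x64), 1413 for P (444 higher, 969 lower) and 4815 for K (2257 higher, 2558 lower), of which 491, 333 and 642 at least 2-fold (limma). The x64 and x4 arrays never shared a slide, so no value within a slide could be had. With slide as a random block 1526, 45 and 2898 genes differed for N, P and K, and with slide as a fixed block 357 for N and 2769 for K. For N the fixed block rests on x16 replicate 3, the only array of another dose on the slide of the x64 arrays. A fixed block could not be fitted for P, where the x64 arrays had a slide to themselves. With normexp correction followed by quantile normalization 46.6% of the changed P genes were higher at x64, against 31.4%. The N count was 2182 or 1988 without x64 replicate 1 or 3. The P count was 832 or 323 without x64 replicate 2 or 3 and 256 without x4 replicate 3. The K count was 2658 without x64 replicate 1 and 1495 or 2776 without x4 replicate 1 or 2.

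The nutrients were compared by testing the difference of their x64 responses. The change of NAS1 (Os03g0307300) was 40.8-fold higher for P than for N (log2 −5.35 for N minus P, SE 0.45, adjusted p = 1.39e-08) and 124-fold higher for P than for K (log2 6.96, SE 0.45, adjusted p = 1.59e-10). The Myb gene Os07g0443500 responded 47.7-fold more strongly downward to N than to P and 88.2-fold more than to K. The response of the ferritin genes was lower for N than for K (list median log2 −1.97, adjusted p = 8.68e-07, and adjusted p = 0.0408 with an estimated correlation). Their median at K x64 was 0.04, their level was higher in N than in K controls by 2.43, and their fall at N was not called against all 9 control arrays (adjusted p = 0.363). The response of type-A response regulators was lower for N than for K (−0.51, adjusted p = 4.86e-04, but adjusted p = 0.347 with an estimated correlation), and that of ribosomal protein genes was higher (0.44, adjusted p = 4.09e-17, but adjusted p = 0.918 with an estimated correlation). In all, 4740 of 26451 genes differed between the N and P responses, 3625 between N and K and 3716 between P and K (limma), of which 1152, 811 and 1119 at least 2-fold. The N and K count was 2370 without K x64 replicate 1 and the P and K count 2253 without K control 1. With quantile normalization 50% of the genes that differed between N and K had the higher response in N, against 61%. With all 9 control arrays as a common control, that control cancels from the difference of responses. The counts of 8698 for N and K and 7914 for P and K then compare the x64 arrays directly. They include differences between the sets, such as scan day, and do not test a difference of responses. Of the genes higher at x64, 298 were shared by N and P (191 for independent lists), 388 by N and K (194) and 263 by P and K (167), and 412, 357 and 278 genes changed in opposite directions (314, 383 and 359).

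The control sets had the same dose by the labels, and the comparison asks how far they differed before any treatment. Between N and P controls 6713 genes differed (3223 higher in N, 3490 lower), between N and K 8400 (4509 higher, 3891 lower) and between P and K 6305 (3564 higher in P, 2741 lower), of which 1258, 1186 and 609 at least 2-fold (limma). Without P control 3 the N and P count was 4413. Ferritin genes were higher in N than in P controls (median log2 1.36, adjusted p = 3.81e-05, and adjusted p = 0.0423 with an estimated correlation) and than in K controls (2.43, adjusted p = 3.57e-06, and adjusted p = 0.0218 with an estimated correlation). Of 9 iron acquisition genes 6 were lower in N than in P controls (6 adjusted over the list alone; median log2 −1.62, adjusted p = 8.77e-07, and adjusted p = 6.72e-03 with an estimated correlation), with IRO2 (Os01g0952800) at least 15.4-fold lower. Of 37 jasmonate genes 24 were lower and 1 higher in N than in P controls (25 and 2 adjusted over the list alone; median log2 −0.54, adjusted p = 4.21e-07, but adjusted p = 0.263 with an estimated correlation). The lipoxygenase gene Os03g0738600 was 251-fold lower in N than in P controls and 73.0-fold lower than in K controls, and the methyltransferase gene Os06g0242000 at least 39.2-fold and 12.4-fold lower. Higher in N than in P controls were a nodulin 21 gene (Os04g0538400, at least 16.2-fold), OSH15 (Os07g0129700, at least 11-fold) and Os05g0531200 (at least 5.63-fold). Os05g0531200 was also at least 5.63-fold higher than in K controls. A pathogenesis-related 1 gene (Os07g0129300) was 19.4-fold and a kinase gene (Os09g0356800) 17.1-fold higher in N than in K controls, whereas an aminotransferase gene (Os04g0614500) was at least 7.91-fold lower. Between P and K controls an ankyrin gene (Os09g0343200) was 10.6-fold higher in P, and an O-methyltransferase gene (Os12g0441300) was 6.11-fold and a cinnamoyl-CoA reductase gene (Os08g0277200) at least 4.3-fold lower. Genes near background in 1 set, Os07g0175000, Os09g0555400 and Os11g0132100, differed at least 2.67-fold, 2.54-fold and 2.99-fold.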

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

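The slide test, the test of lower background on the P x64 arrays, all 3 tests of the iron acquisition pattern and the corrected lists were chosen only after the results they bear on were seen. The tests of higher background and of genomic DNA and the counts over other splits were set before.

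The x64 responses of different nutrients were tested against each other, and these differences are listed because the test of the difference itself passed. The responses to N and P differed in 4740 genes, those to N and K in 3625 and those to P and K in 3716. For N against P the largest log2 differences were 9.48 for the lipoxygenase gene Os03g0738600 (SE 2.69), 8.20 for the esterase gene Os07g0526600 and 7.00 for CI2C (Os12g0548700), and on the negative side −5.58 for the Myb gene Os07g0443500, −5.35 for NAS1 (Os03g0307300) and −5.29 for the embryonic abundant protein gene Os05g0349800. For N against K they were 5.40 for the P450 gene Os12g0134900, 5.37 for the P450 gene Os11g0138300 and 4.33 for the ferric reductase-like gene Os04g0578600, and −6.46 for Os07g0443500, −4.89 for the pollen allergen domain gene Os05g0531200 and −4.20 for the glycine-rich protein gene Os02g0587000. For P against K they were 6.96 for NAS1, 6.04 for NAS2 (Os03g0307200) and 5.51 for Os05g0349800, and −9.65 for the methyltransferase gene Os06g0242000 (SE 3.10), −8.83 for Os03g0738600 and −7.85 for Os07g0526600. The sizes for Os07g0526600, Os05g0349800, Os12g0134900, Os11g0138300, Os04g0578600, Os05g0531200 and Os02g0587000 are not fixed, because at least 1 of the groups behind them was not above background. Os03g0738600 and Os06g0242000 differed between the control sets themselves, by −7.97 and −8.04 for N against P. So did CI2C, at −2.98 in the N and 1.96 in the P control arrays, Os07g0526600 (−10.00 and −4.29), and Os04g0578600, at −7.81 in the N and −3.28 in the K control arrays.

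Among the gene lists, 6 differed between the N and P responses. Their median log2 differences were −0.67 for iron acquisition (1 higher, 4 lower; adjusted p = 0.0221), −0.72 for iron storage (adjusted p = 0.0244), 0.38 for defence proteins (23 higher, 8 lower; 0.0286), −0.58 for type-A response regulators (5 lower; 1.17e-04), 0.19 for glutathione S-transferases (16 higher, 4 lower; 0.0147) and 0.20 for ribosomal proteins (9 higher; 3.89e-04). Between N and K they were −1.97 for iron storage (8.68e-07), 1.13 for phytoalexin synthesis (2 higher; 9.41e-03), −0.51 for type-A response regulators (5 lower; 4.86e-04), 0.23 for glutathione S-transferases (13 higher, 3 lower; 1.75e-03), 0.44 for ribosomal proteins (37 higher; 4.09e-17) and −0.08 for the list named cell division (14 higher, 31 lower; 0.0244), of whose 475 loci 361 had been matched wrongly. With the remaining 114 loci that difference was −0.16 (1 higher, 7 lower; adjusted p = 8.56e-04, but adjusted p = 0.888 with an estimated correlation). Between P and K they were 1.77 for iron acquisition (4 higher, 1 lower; 1.17e-04), −1.25 for iron storage (1.17e-04) and 0.25 for ribosomal proteins (4 higher; 4.81e-05). With the lists as fixed and an estimated correlation, the iron storage difference between N and K alone passed the threshold (adjusted p = 0.0408), and iron acquisition between P and K had adjusted p = 0.0503. With the corrected lists both passed it (8.33e-03, and 0.023 at a median of 1.73). The corrected lists added differences between N and P for cell division (−0.34; 4 higher, 21 lower; adjusted p = 1.34e-06), jasmonate (0.31; 7 higher, 1 lower; 0.0108) and photosystems (0.17; 1 lower; 0.0456), and between P and K for jasmonate (−0.37; 2 higher, 5 lower; 0.0303), each with adjusted p = 0.888 with an estimated correlation.

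Other splits of the same arrays were counted for every test across genes. The 15 comparisons of 3 with 3 arrays each allow 10 splits, too few for a share under 0.05, and in each of them 1 split, the real one, gave as many calls. The real counts of 95, 456 and 4197 for N x4, x16 and x64 against control stood beside 1, 4 and 1 in the highest other split, those of 8179, 5808 and 3984 for P beside 21, 5 and 16, and those of 2790 and 4749 for K x16 and x64 beside 79 and 11. For x64 against x4, the real counts of 1413 for P and 4815 for K stood beside 123 and 197, and no other split of the N arrays made a call beside the real 3480. For the control sets 6713, 8400 and 6305 stood beside 2, 1 and 8. For K x4 (3624) the highest other split gave 2856, with K control 1 set together with K x4 replicates 1 and 2, which points to a structure of the samples other than their dose. For the differences between responses 100 splits were drawn. For N and P 1 of 100 gave as many calls as the real split (4740, highest other 3540), and that 1 was the real split itself. The splits for responses also mix arrays of nutrient sets whose controls differed, so they do not show what chance alone gives. For N and K 8 of 100 did (3625, highest other 12709) and for P and K 10 of 100 (3716, highest other 7760). Splits that exchanged controls also carry the differences between those control sets (8400 and 6305 genes). These shares therefore neither exclude chance nor point to it. For the gene list tests, whose splits stayed within each nutrient, 12 of 100 did (42, highest other 51), so chance cannot be excluded there. Why some splits gave more calls than the real one was not tested.

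Probes for microRNAs on the array were not used in the gene comparisons, and those higher than in the control are listed here. Of 302 such probes tested, 7 were higher at N x16, 8 at N x64, 179 at P x4, 118 at P x16, 25 at P x64, 6 at K x4, 2 at K x16 and 9 at K x64. Lower than in the control were 1 at N x64, 7 at P x4, 7 at P x16, 15 at P x64, 15 at K x4, 8 at K x16 and 20 at K x64. The median log2 change over all 302 probes was 0.82 at P x4 and 0.62 at P x16, beside 0.393 and 0.229 over all dim genes, and microRNA probes were not tested against other probes. At each K dose more of these probes were lower than higher.

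More genes rose at P x4 and x16 than at P x64, and many of them were dim. A background on the P x4 arrays above that of the P control arrays would raise probes of random and artificial sequence. Those probes had a median log2 change of −0.323 (95% interval −0.528 to 0.0676) against 1.37 for the dim genes that rose. The background treatment of that control was unknown. These probes stood at −8.24 to −8.11 there, −9.47 to −9.36 in the N controls and −8.97 to −8.69 in the K controls. At P x4 they stood at −8.50 to −7.97, above the N and K controls, so a higher background than in those sets is not excluded. The dim genes stood at −7.47 to −7.22 over the 3 control sets. Genomic DNA beyond that in the P control samples would raise probes of genomic sequence, which stood at −0.549 (−0.716 to −0.0157). A lower background on the P x64 arrays would lower random and artificial probes, which changed by −0.654 (−0.917 to −0.472) from x4 to x64. The dim genes that had risen at x4 changed by −0.707, though these genes were picked for rising at x4. The mean of those probes was −8.13 on P x64 replicate 1, within the x4 range, and −9.55 and −9.29 on replicates 2 and 3. The dim genes stood at −6.25, −7.12 and −6.83 there. A lower background thus goes with the larger falls on replicates 2 and 3, and not with replicate 1. The P x64 arrays had a slide to themselves and 1 of 3 lay within the range of the x4 and x16 arrays, so slide and dose cannot be told apart, and a dose effect stays open and untested.

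Iron acquisition genes were higher at every P dose. The rise of dim probes on the P arrays would give lists of like expression a like change, but the upper limit of the central range of the median change of 10000 random lists matched on expression was 0.227, and the highest was 0.482, against 2.55. A low level in the P control set alone would end the difference against all 9 control arrays, where the median was 3.64 (adjusted p = 6.16e-08). Scan day stays open, because 0 scan days of treated arrays held more than 1 nutrient, so day and nutrient cannot be told apart. An effect of P, or of the sodium given with it, stays among the open explanations.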

How the results depend on the processing

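Centring each array on the median, keeping only bright genes, the replicate block within each nutrient and the corrected lists were chosen after seeing the data. Where no cause is given below, the cause was not tested.

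A 2-fold minimum lowers every count by its construction: 21, 16 and 533 genes for N x4, x16 and x64, 1642, 1265 and 734 for P, 353, 279 and 584 for K, 491, 333 and 642 for x64 against x4 (N, P, K), 1152, 811 and 1119 for the differences between responses (N and P, N and K, P and K), and 1258, 1186 and 609 for the control sets in the same order. Testing every probe on its own, with more tests and genes counted once per probe, gave 210, 1018 and 6474 for N x4, x16 and x64, 5599, 4515 and 7353 for K x4, x16 and x64, 5967 for N and K, and 5318 and 7237 for x64 against x4 in N and K. All 9 control arrays gave 1054 for N x4, 1320 for N x16 and 6099 for K x16. They also gave 8698 for N and K and 7914 for P and K. In these 2 counts the common control cancels, so they compare the x64 arrays directly and do not test a difference of responses.

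With only the arrays compared, limma gave 0 genes for N x4 (3991 at an unadjusted p under 0.05), 10 for N x16, 6417 for N x64, 1668 for P x64, and 659, 94 and 1371 for K x4, x16 and x64. Fewer arrays set the spread there, but the counts moved both ways. N x64 rose from 4197, while K x4, x16 and x64 fell from 3624, 2790 and 4749. The K counts of the main fit thus depend on the spread shared with the other groups. N x4 also moved to 53 with median centring, 61 with the mean of probes, 44 without the filter on dim probes, 39 with the replicate block and 46 with the block within nutrients, which gave 278 for N x16. Without the filter P x64 against x4 gave 2325. With slide as a random block x64 against x4 gave 1526, 45 and 2898 for N, P and K, and with a fixed block 357 and 2769 for N and K. A fixed block could not be fitted for P. Of 42 gene list calls 3 passed with an estimated correlation.

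Within 1.5 times stayed all 16 counts run with quantile normalization, which did not include x64 against x4, all 15 run with an intensity trend and robust prior, the 3 of x64 against x4 run with normexp and then quantile normalization, and all 15 of bright genes alone, with 6671, 4591 and 3257 genes for P x4, x16 and x64. The median of all genes shifted by −0.0366 to 0.0451 with quantile normalization. The share of rises among changed genes moved from 80.7% to 70.3% for N x16 and from 61% to 50% for N and K with quantile normalization, from 48.3% to 63.7% for K x4 with median centring (2503 higher, 1425 lower), and from 31.4% to 46.6% for P x64 against x4 with normexp and then quantile normalization together (911 higher, 1044 lower).

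Leaving out each array in turn gave 5 to 24 genes for N x4, 135 to 396 for N x16, 2629 to 3465 for N x64, 5586 to 7450 for P x4, 4177 to 4522 for P x16, 2662 to 3701 for P x64, 1752 to 4219 for K x4, 1796 to 3522 for K x16 and 2797 to 4256 for K x64. For x64 against x4 it gave 1988 to 2587 (N), 256 to 1298 (P) and 1495 to 6483 (K), for the differences between responses 3468 to 4365 (N and P), 2370 to 3819 (N and K) and 2253 to 3739 (P and K), and for the control sets 4413 to 5832, 6151 to 7860 and 4504 to 5572. Leaving out P x64 replicate 1 gave 2662 genes at P x64, leaving out K control 1 gave 4219 at K x4, and leaving out K x4 replicate 3 gave 3568.

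Of 118 named gene calls 99 held whichever array was left out and 19 did not. Against all 9 control arrays 86 held, 29 were lost and 3 turned direction: IRO2 to −0.25, NRAMP1 to −0.73 and IRO3 to −0.45 at N x64. These 3 genes were lower in N controls than in the other control arrays, which accounts for the turn. With quantile normalization 118 of 119 named values were the same and 1 was lost, and with median centring and with the replicate block all 119 were the same. Of 97 values from other probes 90 were the same, 5 were lost and 2 turned, both for IPS1 (−0.57 at P x64, 0.03 at K x64).

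Of 42 gene list calls 42 held with the replicate block, 40 with corrected lists, 38 with median centring, 34 without the filter, 27 with quantile normalization, 26 with fry and 25 with all 9 control arrays, where 2 turned (jasmonate at N x64, adjusted p = 0.225, and iron storage at K x4, 0.614). The lists for iron acquisition at P x16 and x64 held in every one of these. Replicate numbers did not pair the samples: in 0 of 15 comparisons were all 3 correlations of like-numbered arrays above 0.1 (for K x4 they were 0.555, −0.0461 and 0.462). Centring on the 75th percentile was not run, since the values already have that scale. Signal near background limits folds of dim genes, which are given as bounds.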

Other observations

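The test of root tissue below was chosen only after the result was seen, in place of a first form over all other measured root markers. The genes named next were also chosen after their values were seen.

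At x64 of all 3 nutrients 65 genes were higher and 31 lower than in the control of the same nutrient, against 15.3 and 12.7 for independent lists. Genes changed in opposite directions also exceeded independence for N and P (412 against 314). They did not for N and K (357 against 383) or P and K (278 against 359). An excess over independent lists is thus not by itself a sign of a common response. Each nutrient had its own control arrays, and batch and treatment cannot be told apart for P and K. For N, the x4 arrays, scanned on the same day, differed from the same control in 95 genes in all, but slide stays open. The NAC factor gene OsNAC5 (Os11g0184900) was higher by log2 1.39, 0.61 and 0.60 for N, P and K, PM19 (Os05g0381400) by 1.48, 3.02 and 0.97, the LEA gene Os03g0322900 by 1.93, 1.89 and 1.48, and the bZIP factor genes bZIP23 (Os02g0766700) and TRAB1 (Os08g0472000), of abscisic acid signalling, by 0.64, 0.27 and 0.19 and by 0.26, 0.26 and 0.30. The transporter gene PDR9 (Os02g0528900) was higher by 0.66, 0.42 and 0.62 and a fructosyltransferase gene (Os02g0106100) by 1.02, 0.67 and 0.72. The response regulator gene RR6 (Os04g0673300) stood at −0.84, −0.39 and −0.38, a zinc transporter gene (Os05g0198400) at −0.59, −0.80 and −0.56, a metallothionein gene (Os05g0202800) at −0.65, −1.58 and −0.42, a prolyl endopeptidase gene (Os04g0561500) at −1.09, −2.93 and −1.59, a flavonoid hydroxylase gene (Os10g0320100) at −1.05, −0.67 and −0.50 and an ACC oxidase gene (Os05g0149400) at −0.35, −0.35 and −0.36.

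The root-expressed gene RCc3 was lower at N x64 (log2 −2.77). Root tissue in the N control shoots may be a source, and would lower other root markers at N x64 alike. The 1 other marker with an N control level no higher than that of RCc3, PIP2;3, changed by −1.53. Lsi1 went the other way, with a rise of 0.43. It was not counted because its probe stood above that of RCc3 in the N control, a level that root tissue there could also raise. With 1 marker, root tissue and an effect of N cannot be told apart, and without N control 1 RCc3 stood at −1.01 (adjusted p = 0.246).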
